A study of Homo sapiens with 9 samples.

How the data were processed

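HepG2 cells were measured on 9 Affymetrix 3' expression arrays, 3 each of vehicle, 10 nM T3 and 10 nM GC-1, all at 24 h. Per the labels' protocols, cells were treated in medium whose serum lacked thyroid hormone, total RNA was extracted with an acid phenol reagent and checked for integrity, and biotin-labelled cRNA was made in a single round of amplification. Groups and replicate numbers were taken from the sample titles.

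The deposited values are log2 signals, 1 per probe set and array. They were made with RMA, per the submitters' processing notes, which give no version. As usually run, RMA corrects background, normalizes the arrays to a common distribution and summarizes the probes of a set, and the arrays nonetheless differed in their interquartile range. The log base is not stated and was inferred from the values, which lie between 3.15 and 14.5 on all arrays, as RMA values on a log2 scale do. Fold changes depend on that base. The values were used as deposited. No scanner files were used, so slide, scan order and the detection of single probe sets were not examined and a dim probe set could not be called absent. RMA signals of dim probe sets are compressed, so fold changes of genes near the lower end are likely understated.

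Of the probe sets 62 were array controls and were left out, which left 22215. The annotation gave 1 gene symbol for 19064 of them, several for 1043 and none for 2108. The Entrez identifiers of 19052 of the 1-symbol probe sets matched the reference gene table, and 0 symbols had to be updated. Only 1-symbol probe sets were named, for 11963 genes, and a gene was represented by its probe set with the highest mean over the 9 arrays. Probe sets of 1 gene can disagree. GSTA1 ranged from 0.04 to 1.64 between its 2 probe sets under T3, SCNN1A from 0.09 to 1.56 over 3, KLF9 from 0.12 to 1.60 over 3, CPT1A from 0.19 to 1.31 over 4 and OSBPL10 from -0.51 to -0.04 over 3. SLC4A4 had 1 of 4 probe sets higher and 1 lower under T3. The probe sets of CD24, SLC4A4, IDI1, PFKL and GAPDH belong to a type that can bind several transcripts.

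Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in 1 linear model of the group means over all 9 arrays, so that the groups share 1 estimate of the spread. Contrasts were T3 minus vehicle, GC-1 minus vehicle, GC-1 minus T3, and the mean of the ligands minus vehicle. With equal groups that vary alike, the estimate of the last one is independent of that of GC-1 minus T3. Their intervals still rest on the same estimate of the spread. The ligand mean was used to choose probe sets for comparing the ligands. T3 arrays varied more than GC-1 arrays (SD of the differences between arrays of a group 0.129 to 0.178 log2 units, against 0.110 to 0.132). The choice may therefore lean toward larger changes under T3. P-values were adjusted by Benjamini-Hochberg over all 22215 probe sets of a contrast, and an adjusted p under 0.05 counted as changed. Standard errors come from the same model, and 95% confidence intervals were computed for GC-1 minus T3. A probe set counted as alike in both ligands when that interval lay within 1.5-fold.

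The response score of an array is the mean, over the probe sets changed in the ligand mean, of its log2 difference from the vehicle mean with the sign of the change. The scores of T3 and GC-1 arrays were compared by an exact permutation test. The correlation of the T3 and GC-1 changes was set beside 100 simulations of unchanged groups that share 3 vehicle arrays. The overlap and the same-sign share were set beside lists of the observed sizes, taken in each direction from the largest changes of those simulations.

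The 18 gene lists, the contrasts, the margin, the rule for named genes and the alternatives not marked as later additions were chosen before the data were examined. Lists were tested with camera (preset correlation 0.01), with an estimated correlation as an alternative, adjusted over the 18 lists of a contrast. They cover thyroid hormone targets, hormone transport and receptors, fatty acid synthesis, cholesterol synthesis and uptake, bile acid, lipoprotein and sterol export, fatty acid oxidation, glucose metabolism, oxidative phosphorylation, coagulation, the acute phase, hepatocyte identity, the cell cycle, endoplasmic reticulum stress and amino acid response, hypoxia and glycolysis, drug metabolism, Wnt, TGF-beta and growth factors, other cell types, and housekeeping. Some genes belong to several lists.

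The genes named are those with the 10 largest increases and 10 largest decreases in each ligand comparison among genes past the threshold whose 3 ligand arrays all lay on one side of the 3 vehicle arrays. For GC-1 against T3, where no gene passed, they are the 5 with the smallest p. THRSP, KLF9, DIO1, HR, CPT1A, PCK1, THRA and THRB were named whatever they showed, and up to 4 genes of each list with the smallest p in the ligand mean. Further list members named to say which genes a count of passing members holds, and CDH1, POU4F2, WNT6, PKP4, SPEN and DICER1, were chosen after their values were seen.

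Alternatives were quantile normalization, subtraction of array medians, leaving out probe sets whose mean lay below the 40th percentile (6.51 on the log2 scale), eBayes with trend and robust options, array weights, the replicate number as a block, only the 2 groups compared, a change of at least 1.5-fold, 1 probe set per gene, averaged probe sets, fry in place of camera, and leaving out each array in turn. Added after seeing the data were a fit with T3 replicates 1 and 2 left out, the interquartile range of the array as a covariate, and quantile normalization together with leaving out T3 replicate 3.

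The fit was tested on simulated data. In T3 minus vehicle it recovered 37.3% of 1.2-fold changes and 100% of 1.5-fold and 2-fold changes among 22215 probe sets. In GC-1 minus T3 it recovered 46.3% of 1.2-fold, 98.5% of 1.5-fold and 100% of 2-fold changes, and in GC-1 minus vehicle 37.3%, 100% and 100%. False calls were 3.07%, 4.12% and 2.47% of calls in T3 minus vehicle, GC-1 minus T3 and GC-1 minus vehicle. For the list test, sets of 25 genes among 11963 were simulated in T3 minus vehicle. Of the sets shifted by 0.2 log2 units 20 of 20 were found, and 14 of 400 unshifted sets had a camera p under 0.05. The simulated genes varied independently, so these counts do not show how the test behaves where genes of a list are correlated. Figures were drawn with matplotlib.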

Results

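Messenger RNA levels were measured with Affymetrix expression arrays in HepG2 cells, an established human line grown from a liver tumour that keeps many functions of hepatocytes. The cells were moved to medium whose serum lacked thyroid hormone and given vehicle, 10 nM of the thyroid hormone triiodothyronine (T3) or 10 nM of GC-1 for 24 h. GC-1, also called sobetirome, is a synthetic ligand of the thyroid hormone receptors that binds the beta form with preference. It differs from T3 in that methyl groups stand in place of the inner-ring iodines and an isopropyl group in place of the outer-ring iodine. A methylene bridge replaces the ether oxygen between the rings, and an oxyacetic acid replaces the amino acid side chain. Each group held 3 arrays, 9 in all, and the values were log2 signals of 22215 probe sets that are not array controls. The series asks how closely the genes regulated by GC-1 match those regulated by T3.

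Array medians ranged from 7.02 to 7.06 on the log2 scale. The 3 vehicle arrays lay together on the first principal component, at -12.8, -11.5 and -11.7, and all 6 ligand arrays lay between 1.58 and 14.1. The T3 arrays did not form a tight group. T3 replicates 1 and 2 stood at -14.6 and -11.8 on the second component, while T3 replicate 3 stood at 6.59, among the GC-1 arrays at 3.15 to 8.30. On the first component, however, T3 replicate 3 stood at 14.1, beyond the GC-1 arrays at 1.58 to 7.29. The interquartile range of T3 replicates 1 and 2 was 2.99 and 2.97 log2 units, against 2.83 to 2.88 for the other 7 arrays. Array controls at the 3' and 5' ends of GAPDH and ACTB differed least on GC-1 replicate 1 and T3 replicate 3. The differences were 0.170 and 0.188 log2 units in GAPDH (others 0.204 to 0.265) and 0.083 and 0.123 in ACTB (others 0.135 to 0.281). Whether this relates to the place of these arrays on the components was not tested. No pair of arrays held identical values throughout, and the number of arrays limits the precision. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

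**Figure D1:**
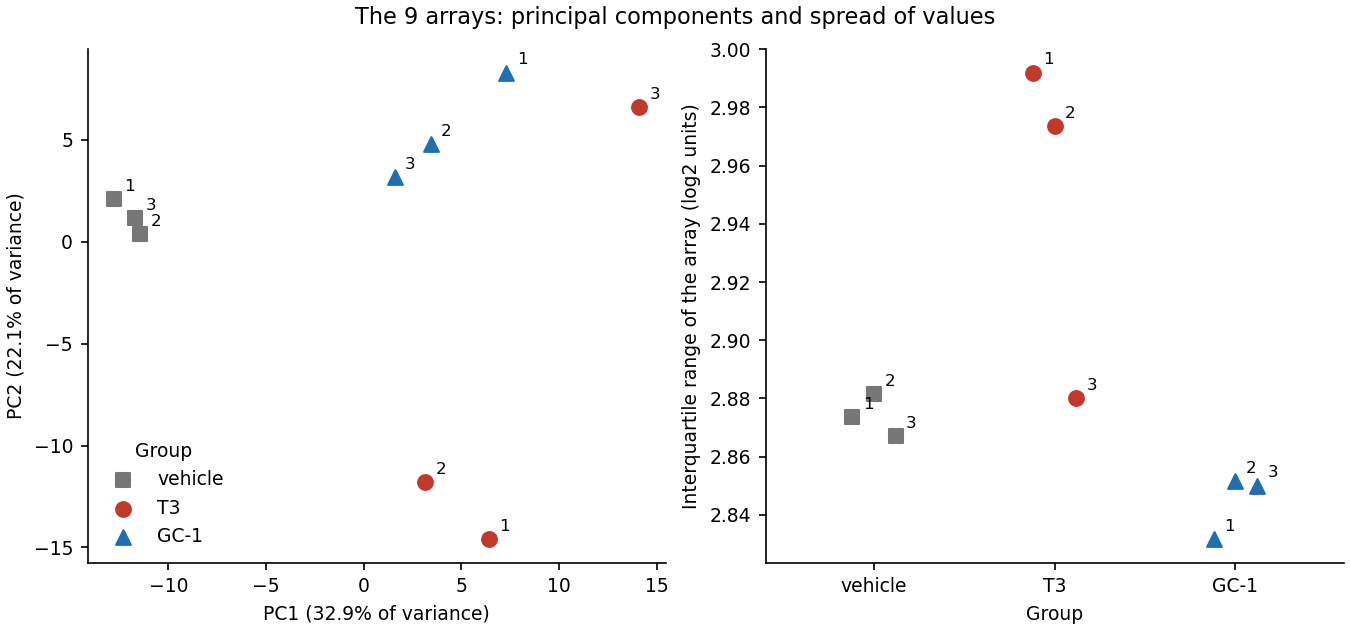
Left, the 9 arrays on the first and second principal components of all probe sets, with 32.9% and 22.1% of the variance; colours and symbols mark the groups and digits the replicates. Right, the interquartile range of each array in log2 units; T3 replicates 1 and 2, at 2.99 and 2.97, lie above the other 7 arrays.

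The first comparison asks which genes T3 changed. The largest increase was in G6PC1, the glucose-releasing phosphatase of the liver, which rose 5.40-fold (log2 2.43 ± 0.13 SE, n = 3 per group, adjusted p = 1.22e-06). PCK1, a rate-controlling enzyme of glucose synthesis, rose 2.72-fold, and SLC2A1, the glucose transporter GLUT1, fell 1.86-fold. ANGPTL8, a secreted regulator of lipoprotein lipase, rose 3.19-fold (log2 1.67 ± 0.05, adjusted p = 1.41e-08), and CPT1A, which admits fatty acids into mitochondria, rose 2.49-fold. HAMP, the iron hormone hepcidin, rose 2.47-fold, and KLF9, a transcription factor known as a direct thyroid hormone target, rose 2.24-fold.

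The 10 largest increases, which leave out KLF9, also held GSTA1 (3.11-fold), SCNN1A (2.95-fold), TNFSF10 (2.83-fold), C8B (2.31-fold) and UGT2B4 (2.30-fold). GSTA1 and UGT2B4 encode conjugating enzymes, SCNN1A a subunit of the epithelial sodium channel, TNFSF10 the death ligand TRAIL, and C8B a chain of complement component 8. The 10 largest decreases were smaller. CEMIP, a hyaluronan-degrading protein, fell 1.91-fold (log2 -0.93 ± 0.06, adjusted p = 4.67e-06). HS3ST3A1, TENT5A and the transcription factor GATA6 fell 1.77-fold, 1.66-fold and 1.65-fold, CD24 and SCGN 1.58-fold and 1.57-fold. PCYT1B, SERPINE2 and OSBPL10 fell 1.45-fold, 1.43-fold and 1.43-fold. By the rule of choice, all 3 T3 arrays lay on one side of all 3 vehicle arrays in every one of these genes.

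Of a list of 30 known thyroid hormone targets, 26 were measured, and 9 of them rose with T3 while none fell; 14 rose with p adjusted over the list alone. The list stood above other genes (adjusted p = 3.18e-09, camera; 0.00794 with an estimated correlation), with G6PC1, PCK1, CPT1A and KLF9 in front. ANGPTL4, an inhibitor of lipoprotein lipase, rose 2.02-fold, and DIO1, the deiodinase that activates and clears thyroid hormone, rose 1.65-fold. The list was drawn from general knowledge, which may include work on these same cells. The receptor genes THRA and THRB had log2 differences of -0.07 (adjusted p = 0.511) and -0.14 (adjusted p = 0.655), and HR, another known target, 0.01 (adjusted p = 0.962). In the list of hormone transport and receptor genes, 2 of 23 measured genes rose, DIO1 and the transporter SLC7A5, and also 2 over the list alone (list adjusted p = 0.0356; adjusted p = 0.0835 with an estimated correlation). THRSP was not analysed here because no probe set named it alone.

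Genes of glucose metabolism rose as a list, with 7 of 22 measured members higher and 1, SLC2A1, lower (13 and 1 adjusted over the list alone; list adjusted p = 4.92e-06). PCK2, the mitochondrial form of PCK1, rose by 0.54 on the log2 scale and FOXO1, a transcription factor restrained by insulin, by 0.41. The same list holds glycolytic genes that also rose, such as PKLR (0.41) and PFKL (0.27), so its members do not all belong to glucose synthesis. Of the hypoxia and glycolysis list, 12 of 27 rose and only SLC2A1 fell (19 and 1 over the list alone; list adjusted p = 2.09e-11). ADM (0.58), VEGFA (0.44), P4HA1 (0.44) and NDRG1 (0.41) were among them. Fatty acid oxidation had 3 of 22 members higher, CPT1A, HADHA and ECI2, and 10 over the list alone (list adjusted p = 8.79e-06; adjusted p = 0.0517 with an estimated correlation). Fatty acid synthesis had 2 of 16 higher, MLXIPL (0.51) and PNPLA3 (0.40), and 2 over the list alone (list adjusted p = 0.00910; adjusted p = 0.0517 with an estimated correlation).

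Of 24 measured coagulation genes 13 rose and none fell (15 and 1 over the list alone; list adjusted p = 2.96e-12), among them the fibrinogen chains FGA (0.86 ± 0.06) and FGB (0.69 ± 0.05), heparin cofactor SERPIND1 (0.65) and antithrombin SERPINC1 (0.54). Acute phase genes rose in 9 of 23 cases (9 over the list alone; list adjusted p = 3.76e-06; adjusted p = 0.0788 with an estimated correlation), with haptoglobin HP at 0.73 and ORM1 at 0.62 beside HAMP. Bile acid, lipoprotein and sterol export genes rose in 7 of 20 cases (10 over the list alone; list adjusted p = 6.59e-07), led by the phospholipid exporter ABCB4 (0.66) and the apolipoprotein APOC3 (0.48). Hepatocyte identity genes rose in 5 of 19 cases (5 over the list alone; list adjusted p = 2.01e-06), with CEBPB at 0.81 and CEBPA at 0.48. In the drug metabolism list 8 of 27 rose and 1, SULT1E1, fell (13 and 1 over the list alone; list adjusted p = 8.13e-05). CYP4F3 rose 2.08-fold and CYP3A5 1.89-fold.

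Other lists moved little. Among cell cycle genes 2 of 40 fell, CDK2 (-0.21) and E2F1 (-0.33), 3 over the list alone (list adjusted p = 0.00551; adjusted p = 0.302 with an estimated correlation). Oxidative phosphorylation had 2 of 46 higher, CYC1 and NDUFA2, and 3 over the list alone (list adjusted p = 0.00257; adjusted p = 0.320 with an estimated correlation). The endoplasmic reticulum stress and amino acid response list had 1 of 26 higher, HERPUD1 (0.43), and 1 over the list alone (list adjusted p = 0.0113; adjusted p = 0.160 with an estimated correlation). Cholesterol synthesis and uptake had 0 of 19 past the threshold, also over the list alone (list adjusted p = 0.506; median just below zero, mean just above it and test pointing up), with IDI1 at -0.10, MSMO1 at 0.13 and FDPS at 0.16. Wnt, TGF-beta and growth factor genes had 3 of 29 higher and 2 lower (5 and 3 over the list alone), ID2 and IGFBP3 among the first and ID3 and SPRY2 the second. Their median was -0.03 while the mean was 0.03 and the test pointed up (adjusted p = 0.506). The markers of other cell types, 19 measured, held 1 gene that rose and 1 that fell, also over the list alone (list adjusted p = 0.881; median near zero and test pointing down, mean 0.02). These were CD14 (2.25-fold higher), a monocyte receptor that hepatocytes also make, and SFN (-0.24), while CDH5 and PTPRC lay at 4.83 and 4.88 in vehicle. None of 12 housekeeping genes passed, also over the list alone (list adjusted p = 0.506), with GAPDH at 0.10.

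In all, limma called 1222 probe sets changed by T3 at an adjusted p under 0.05, 888 higher and 334 lower, and 121 of them changed at least 1.5-fold, 109 higher and 12 lower. The interquartile range of the array varied within groups mainly in T3 (2.99, 2.97 and 2.88). A fit with it as a covariate therefore rests for T3 largely on replicate 3. With this covariate, chosen after seeing the data, the excess of increases was lost (932 higher, 1152 lower). A fit with T3 replicates 1 and 2 left out, also chosen then, had 850 higher and 980 lower, but it holds 1 T3 array, assumed to vary like the other groups. All 3 T3 arrays lay on one side of all 3 vehicle arrays in 24.9% of probe sets, where chance gives 10%. Without vehicle replicate 1, 2 or 3 the count was 661, 746 or 672, and without T3 replicate 1 it was 779. Of 18 lists, 14 passed with the preset correlation and 7 with an estimated one. With the preset one, 10 passed after quantile normalization, 12 without dim probe sets and 11 with the covariate. The hormone transport list did not pass without vehicle replicate 3 (adjusted p = 0.0597), T3 replicate 1 (adjusted p = 0.0870) or T3 replicate 3 (adjusted p = 0.0564), nor the endoplasmic reticulum stress list without T3 replicate 1 (adjusted p = 0.0656).

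**Figure D2:**
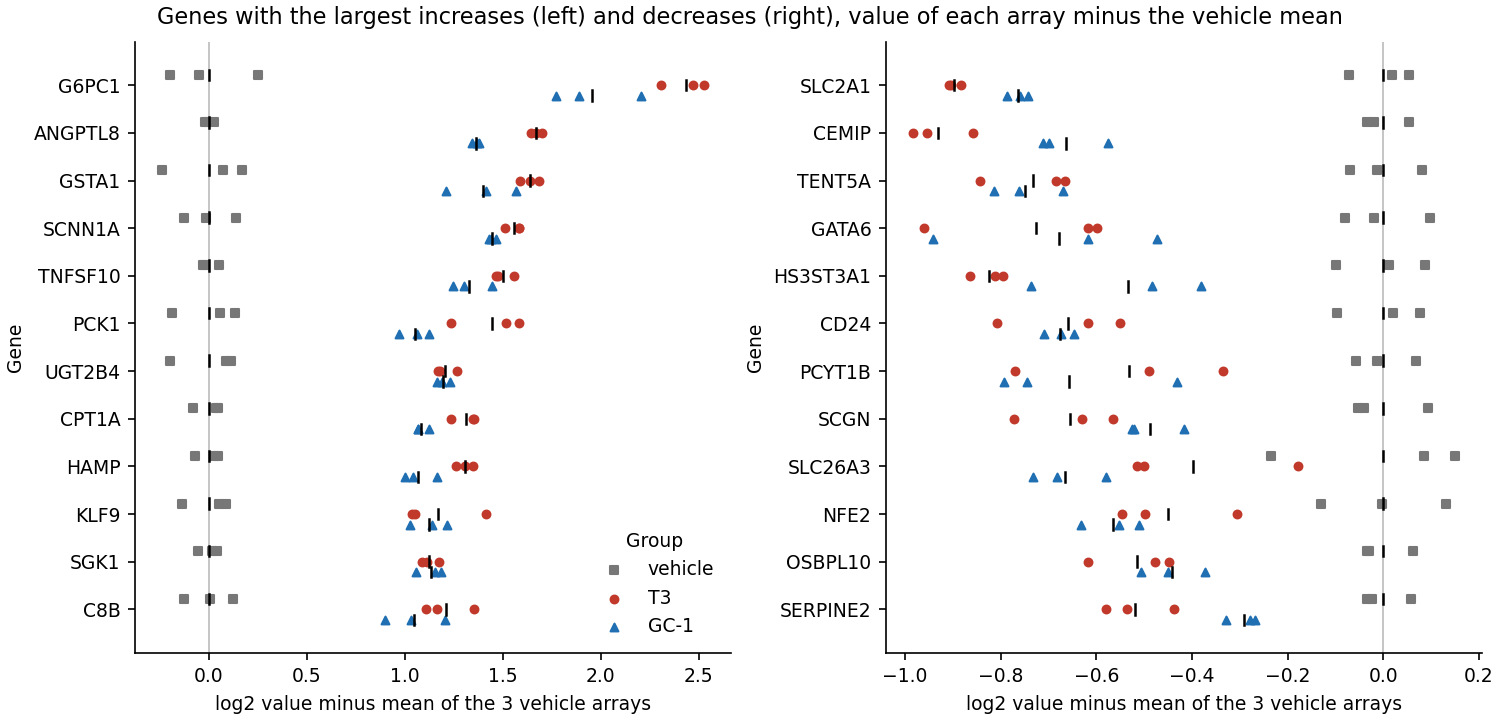
Value of each array minus the mean of the 3 vehicle arrays, in log2 units, for the genes with the largest increases (left) and decreases (right) under T3 or GC-1; points are arrays and the short bars are group means. G6PC1 stands at 2.43 with T3 and 1.96 with GC-1, and SLC2A1 at -0.90 and -0.76.

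The second comparison asks which genes GC-1 changed at the same dose and time. The gene with the largest increase was again G6PC1, which rose 3.88-fold (log2 1.96 ± 0.13, n = 3 per group, adjusted p = 1.02e-05). SCNN1A rose 2.72-fold, GSTA1 2.63-fold, ANGPTL8 2.57-fold (log2 1.36 ± 0.05, adjusted p = 9.33e-08), TNFSF10 2.51-fold and UGT2B4 2.29-fold. SGK1, a kinase that regulates sodium channels, rose 2.19-fold, KLF9 2.18-fold, CPT1A 2.12-fold and HAMP 2.10-fold. SLC2A1 fell 1.70-fold, the largest decrease among the genes named by the rule (log2 -0.76 ± 0.05, adjusted p = 1.02e-05). TENT5A, CD24 and GATA6 followed at 1.68-fold, 1.60-fold and 1.60-fold lower.

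The rest of the 10 largest decreases were SLC26A3, a chloride exchanger (1.59-fold), PCYT1B and CEMIP (1.58-fold each), NFE2 (1.48-fold), HS3ST3A1 (1.45-fold) and SCGN (1.40-fold). By the rule of choice, all 3 GC-1 arrays lay on one side of all 3 vehicle arrays in these genes. SLC26A3 had a log2 difference of -0.40 with T3 (adjusted p = 0.0635). PCK1 rose 2.07-fold and DIO1 1.58-fold with GC-1. THRA had a log2 difference of -0.06 (adjusted p = 0.620), THRB of -0.35 (adjusted p = 0.306) and HR of -0.03 (adjusted p = 0.915).

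Of the 26 measured thyroid hormone targets 7 rose and none fell with GC-1, and 12 rose and 2 fell over the list alone (list adjusted p = 2.33e-08). ANGPTL4 rose by 0.70 and SULT2A1, a sulfotransferase for steroids, by 0.51. Glucose metabolism had 5 of 22 higher and SLC2A1 lower (9 and 1 over the list alone; list adjusted p = 0.000719), with PCK2 at 0.36. Coagulation genes rose in 7 of 24 cases (11 over the list alone; list adjusted p = 3.85e-09), with FGA at 0.75, FGB at 0.65 and SERPIND1 at 0.56. Bile acid, lipoprotein and sterol export genes rose in 5 of 20 cases (8 over the list alone; list adjusted p = 2.52e-06), with ABCB4 at 0.54 and NR0B2 at 0.34. Hepatocyte identity genes rose in 3 of 19 cases (4 over the list alone; list adjusted p = 4.18e-06), with CEBPB at 0.72. Drug metabolism genes rose in 6 of 27 cases (12 higher and 2 lower over the list alone; list adjusted p = 2.43e-06), with CYP3A5 2.01-fold and CYP4F3 1.81-fold higher. These 6 lists also passed with an estimated correlation.

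Another 4 lists passed with the preset correlation alone. Acute phase genes had 6 of 23 higher and 1, CCL20, lower (8 and 1 over the list alone; list adjusted p = 2.43e-06; adjusted p = 0.0904 with an estimated correlation), with HAMP, HP (0.60) and ORM1 (0.50) in front. Hypoxia and glycolysis genes had 4 of 27 higher and 1 lower (12 and 1 over the list alone; list adjusted p = 2.60e-06; adjusted p = 0.114 with an estimated correlation), the 4 being ADM, VEGFA, P4HA1 and P4HA2. Fatty acid oxidation had 1 of 22 higher, CPT1A, and 1 over the list alone (list adjusted p = 0.00227; adjusted p = 0.134 with an estimated correlation). Cell cycle genes had 3 of 40 lower, TYMS (-0.23), MCM4 (-0.26) and CDC20 (-0.24), and 17 lower over the list alone (list adjusted p = 2.07e-09; adjusted p = 0.0596 with an estimated correlation).

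The other 8 lists did not pass with GC-1. Hormone transport and receptor genes had 1 of 23 higher, DIO1, 2 over the list alone (list adjusted p = 0.0884), and fatty acid synthesis 1 of 16 higher, MLXIPL at 0.37, 1 over the list alone (list adjusted p = 0.187). Endoplasmic reticulum stress and amino acid response genes had 2 of 26 higher, HERPUD1 (0.41) and VLDLR (0.29), 2 over the list alone (list adjusted p = 0.0603). Cholesterol synthesis and uptake (adjusted p = 0.626), oxidative phosphorylation (adjusted p = 0.808) and housekeeping (adjusted p = 0.838) had 0 genes past the threshold, also over the list alone. Wnt, TGF-beta and growth factor genes had 2 of 29 higher and 3 lower, 7 and 3 over the list alone (adjusted p = 0.674; median -0.03, mean 0.01, test pointing up). Markers of other cell types had CD14 higher (2.07-fold) and SFN lower (-0.28), 2 and 1 over the list alone (adjusted p = 0.166).

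GC-1 changed 622 probe sets at an adjusted p under 0.05 in limma, 403 higher and 219 lower, and 86 of them at least 1.5-fold, 73 higher and 13 lower. All 3 GC-1 arrays lay on one side of all 3 vehicle arrays in 26.5% of probe sets, where chance gives 10%. The count was 285, 287 or 292 without vehicle replicate 1, 2 or 3, 274, 276 or 284 without GC-1 replicate 1, 2 or 3, and 1272 without T3 replicate 3, which enters the shared estimate of the spread. Of those 1272, 602 were higher and 670 lower, so the excess of increases was lost. The endoplasmic reticulum stress list passed without vehicle replicate 2 (adjusted p = 0.0428) or GC-1 replicate 2 (adjusted p = 0.0406).

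**Figure D3:**
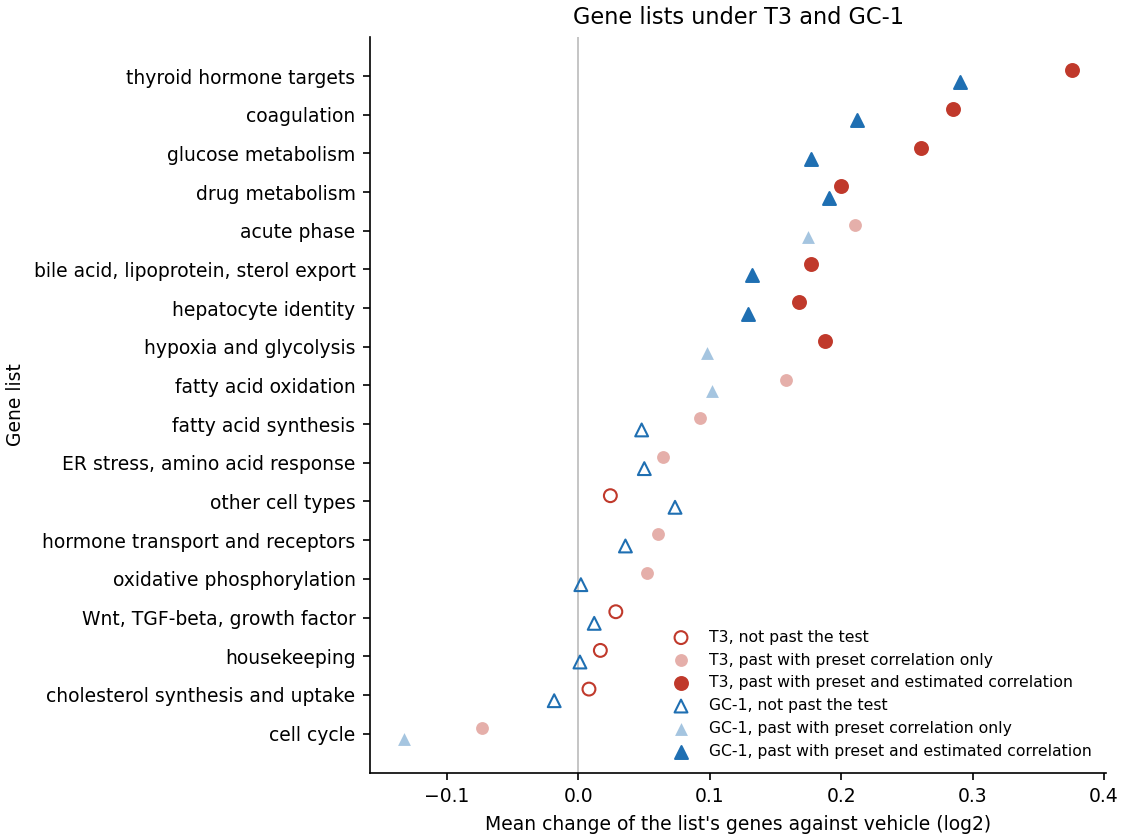
Mean log2 change against vehicle of the measured genes of each of 18 lists, for T3 (circles) and GC-1 (triangles). Filled symbols passed camera with a preset and an estimated correlation, pale symbols with the preset one alone, and open symbols did not pass; the thyroid hormone targets lie highest, at 0.38 with T3 and 0.29 with GC-1.

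The third comparison sets GC-1 against T3 directly, at the matched dose and time, and asks in which genes the ligands differ in effect. No probe set differed at an adjusted p under 0.05 in limma, and 3122 had an unadjusted p under 0.05, where chance gives 1111. All 3 GC-1 arrays lay on one side of all 3 T3 arrays in 18.0% of probe sets, where chance gives 10%. The absence of calls therefore does not show that the ligands act alike. The trend and robust options of eBayes called 22, and array weights 0. The smallest adjusted p was 0.143, shared by several probe sets, among them those of SLC4A4, whose GC-1 minus T3 difference was 0.37 on the log2 scale (95% interval 0.25 to 0.48), and ANGPTL8 (-0.31, interval -0.41 to -0.21). The other 3 of the 5 named genes with the smallest p were EMILIN1 (-0.31, interval -0.41 to -0.20), ADM (-0.31, interval -0.42 to -0.20) and HAL, a histidine-degrading enzyme (-0.53, interval -0.73 to -0.34). None of these passed, with adjusted p from 0.143 to 0.163.

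Several large responses had intervals that reached close to equality. The difference was -0.01 in UGT2B4 (interval -0.18 to 0.16), 0.01 in SGK1 (-0.11 to 0.13), -0.04 in KLF9 (-0.26 to 0.18), -0.06 in DIO1 (-0.19 to 0.06) and -0.02 in TENT5A (-0.16 to 0.13). It was 0.09 in CYP3A5 (-0.09 to 0.26). Others lay lower in GC-1 with intervals that leave out zero, though no adjusted p passed: G6PC1 at -0.48 (-0.75 to -0.20), PCK1 at -0.39 (-0.61 to -0.17), CPT1A at -0.23 (-0.35 to -0.11) and HAMP at -0.24 (-0.37 to -0.11). THRA, THRB and HR differed by 0.00 (-0.11 to 0.12), -0.20 (-0.55 to 0.14) and -0.04 (-0.24 to 0.16). These intervals are not adjusted for the number of probe sets.

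The ligands were compared over probe sets that changed in their mean, a choice that may lean toward T3, whose arrays varied more. These were 1228 probe sets, 806 higher and 422 lower than in vehicle. That balance turned to 1171 higher and 1458 lower with the covariate. It was 1066 higher and 1402 lower with T3 replicates 1 and 2 left out, where 1 T3 array remains. In 1223 of them, or 99.6%, the 95% interval of the GC-1 minus T3 difference lay within a 1.5-fold margin set in advance. This margin is wide beside a median change of 0.27 log2 units, and 99.8% of all 22215 probe sets, changed or not, also lay within it. The share thus says little about the changed ones in particular. The choice by adjusted p also favours probe sets with little spread, whose intervals reached a median of 0.127 log2 units to each side, against 0.145 over all. Among the 107 that changed at least 1.5-fold, 103 (96.3%) lay within it. The 5 exceptions were G6PC1, PCK1, HAL, CDH1 and a probe set with no gene named, all with the larger change under T3.

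The mean signed change over the 1228 probe sets was 0.356 ± 0.030 log2 units (SD, n = 3) on the T3 arrays and 0.300 ± 0.014 (SD, n = 3) on the GC-1 arrays, or 84.4% of the T3 value. All 3 GC-1 arrays lay below all 3 T3 arrays (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 arrays can give). GC-1 gave the smaller change in 71.9% of the 1228 probe sets and in 83.2% of the 107. Over all 22215 probe sets, changed or not, the share was 56.0%. The choice of probe sets may widen the gap between the ligands in the 1228 and the 107. The measured difference was -0.0192 over the probe sets called with the interquartile range of the array as a covariate.

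**Figure D4:**
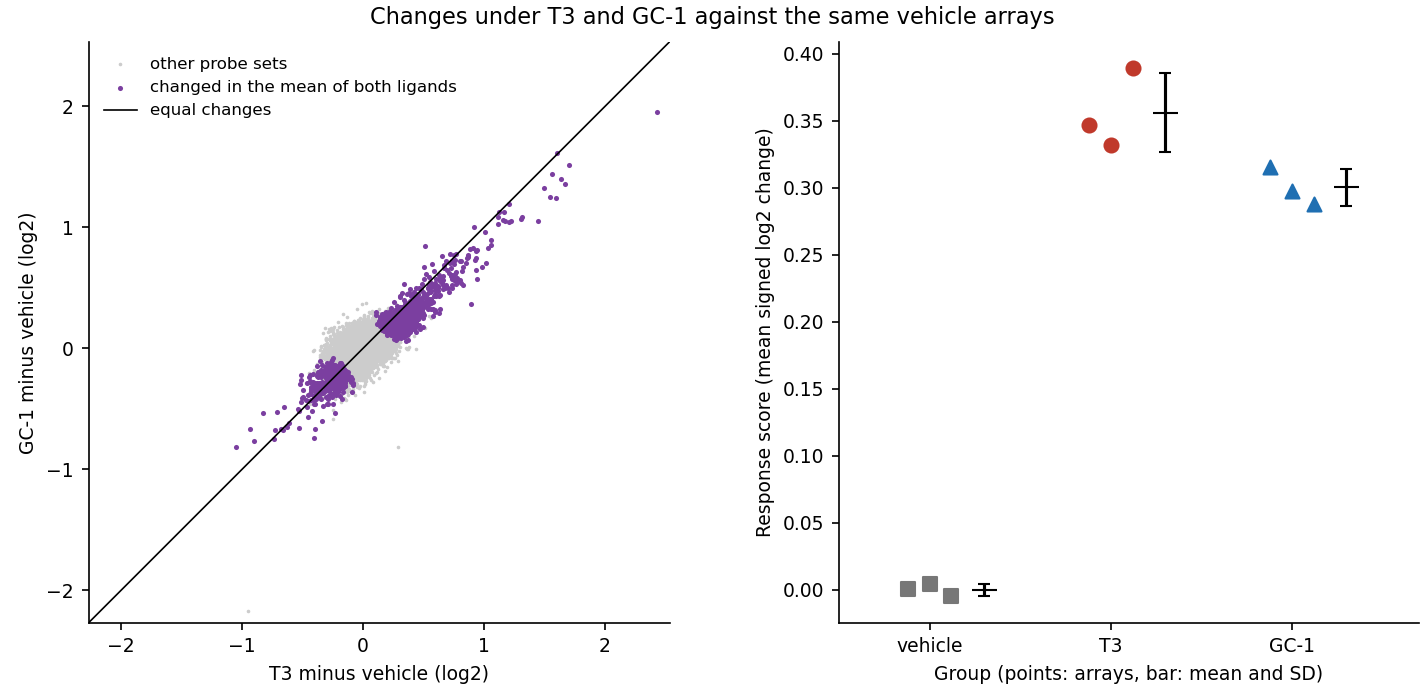
Left, log2 change under T3 (horizontal) and GC-1 (vertical) of each of 22215 probe sets against the same 3 vehicle arrays; purple points changed in the mean of both ligands and the line marks equal changes. Right, the mean signed log2 change over the 1228 purple probe sets on each array, with the mean and SD of 3 arrays beside the points; T3 arrays average 0.356 and GC-1 arrays 0.300.

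As lists, thyroid hormone targets, fatty acid oxidation, glucose metabolism, oxidative phosphorylation, coagulation, cell cycle, and hypoxia and glycolysis genes lay lower in GC-1 than in T3 with the preset correlation. Their adjusted p ran from 0.000281 for hypoxia and glycolysis to 0.0166 for fatty acid oxidation, and none of the 7 passed with an estimated correlation. That estimate gave adjusted p = 0.123 for the thyroid hormone targets and for glucose metabolism. It gave adjusted p = 0.333 with an estimated correlation for oxidative phosphorylation, and adjusted p = 0.253 with an estimated correlation for the other 4. The median differences were small, from -0.0425 in oxidative phosphorylation to -0.0890 in glucose metabolism. Over the list alone 4 thyroid hormone targets, 2 fatty acid oxidation, 3 glucose metabolism, 1 coagulation and 4 hypoxia and glycolysis genes were lower, and 0 of the oxidative phosphorylation and cell cycle genes. Adjusted over all probe sets, no member of any list passed. Drug metabolism genes (adjusted p = 0.893) and the hormone transport and receptor genes (adjusted p = 0.489) did not differ as lists, with medians of -0.00133 and -0.0150.

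The remaining 9 lists did not pass in this comparison, with adjusted p from 0.0662 for bile acid, lipoprotein and sterol export genes to 0.621 for housekeeping genes. Over the list alone 1 bile acid, lipoprotein and sterol export gene was lower, 1 acute phase gene was higher and 1 lower, and no gene of the other lists passed. Wnt, TGF-beta and growth factor genes had a median of 0.01, a mean of -0.02 and a test pointing down.

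Without T3 replicate 3, 338 probe sets differed between GC-1 and T3, 157 higher and 181 lower in GC-1, and 3 lists passed. These were the cell cycle list, the hypoxia and glycolysis list, and markers of other cell types, which lay higher in GC-1 (adjusted p = 0.0457). Thyroid hormone targets (adjusted p = 0.0732), fatty acid oxidation (0.147), glucose metabolism (0.106), oxidative phosphorylation (0.112) and coagulation (0.106) then did not pass. Bile acid, lipoprotein and sterol export and acute phase genes passed without T3 replicate 2 (adjusted p = 0.0179 and 0.0255) or GC-1 replicate 1 (0.0309 and 0.00760). Cholesterol synthesis and uptake passed without T3 replicate 2 (0.0179), fatty acid synthesis without GC-1 replicate 1 (0.0392), and markers of other cell types without GC-1 replicate 2 (0.0490). With T3 replicates 1 and 2 left out, which leaves 1 T3 array, 0 probe sets and 9 lists passed. Of the genes named by the rule, PCK1, HAL, ANGPTL4 and ANGPTL8 were among those called lower in GC-1 without T3 replicate 3, and SLC4A4 was called higher.

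The overlap of the separate calls was also counted. Of the 403 probe sets that rose with GC-1, 373 (92.6%) also rose with T3, where independent lists would share 16.1. Of the 219 that fell with GC-1, 105 (47.9%) also fell with T3, where independent lists would share 3.29. G6PC1, ANGPTL8, CPT1A and KLF9 were among the first and SLC2A1, CEMIP and CD24 among the second. No probe set was called in opposite directions, and 97.4% of the 1366 called with either ligand had the same sign with both. Lists of the same sizes, taken from the ends of 100 simulations without any effect on the same vehicle arrays, shared 109 higher and 37.2 lower probe sets and had the same sign in 89.9%. Across probe sets, which are not independent replicates, the T3 and GC-1 changes had r = 0.708, and r = 0.499 in those simulations. The covariance was 0.0127, against 0.00259 simulated, a difference of 0.0101. The 3 vehicle arrays were not split, since 1 part would keep a single array, so part of the excess in overlap may come from the shared vehicle arrays.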

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

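Among the tests in this part, the deviation and the response score of T3 replicate 3, the reading of the score after quantile normalization, and quantile normalization without T3 replicate 3 were chosen only after the result was seen.

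The 7 lists that lay lower in GC-1 than in T3 differ between the ligands by a direct test of the difference with the preset correlation, and none of them with an estimated one. The median log2 difference was -0.0642 for thyroid hormone targets, -0.0558 for fatty acid oxidation, -0.0890 for glucose metabolism, -0.0425 for oxidative phosphorylation, -0.0848 for coagulation, -0.0598 for the cell cycle and -0.0710 for hypoxia and glycolysis. Against vehicle the cell cycle list fell with both ligands with the preset correlation, while 5 of the other lists rose with both and oxidative phosphorylation passed with T3 alone. The cell cycle list had adjusted p = 0.302 with T3 and 0.0596 with GC-1 with an estimated correlation, and fatty acid oxidation adjusted p = 0.0517 and 0.134 with an estimated correlation. Hypoxia and glycolysis had adjusted p = 0.114 with GC-1 and oxidative phosphorylation adjusted p = 0.320 with T3 with an estimated correlation. SLC4A4, a bicarbonate transporter, stood out because all 3 T3 arrays lay below and all 3 GC-1 arrays above the vehicle arrays. Its difference of 0.37 did not pass the direct test (adjusted p = 0.143), its 4 probe sets disagree, and the one used here is of a type that can bind several transcripts.

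Other splits of the arrays were counted. For T3 against vehicle the real split called 1222 probe sets and the highest of the other splits 0, for GC-1 against vehicle 622 and 0, and for GC-1 against T3 0 and 0. As many calls came from 1, 1 and 10 of the 10 splits. For the lists the real splits gave 14, 10 and 7 past the threshold and the highest others 12, 11 and 8, with as many lists in 1, 2 and 2 of the 10 splits. With 10 splits no share under 0.05 can be reached. The list test with a preset correlation thus passed many lists in groupings that are not the study's. Each of those mixes arrays of both groups in unequal parts, however, so it keeps part of their difference and widens the spread. Neither the lists nor the calls of such splits show what groupings without any effect would give. For the ligand mean 840 splits of the 9 arrays exist, of which 100 were drawn with the real one. Only the real split gave 1228 calls or more. The highest other gave 923, also kept the 3 vehicle arrays together, and was the only other with any call. Splits that mix vehicle and ligand arrays widen the spread and so call little. Ranking first of 100 draws makes chance unlikely there but does not exclude it.

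The first pattern weighed is the set of 338 calls between GC-1 and T3 that appears without T3 replicate 3. Of the 157 calls higher in GC-1, 62.4% lay below the dim limit of 6.51, against 13.3% of the 181 lower ones. POU4F2 and WNT6 were among the 157, and HAL, PCK1, PKP4, SPEN and DICER1 among the 181. T3 replicate 3 lay above the GC-1 mean in HAL (0.376) and PCK1 (0.184). It lay below that mean, against the direction of the call, in PKP4 (-0.187), SPEN (-0.104) and DICER1 (-0.202). GC-1 RNA on T3 replicate 3 stays open, since its response score lay 6.39 SDs of the 3 GC-1 arrays above their mean, but over all probe sets its closest array was GC-1 replicate 1 (SD of the differences 0.132 log2 units, against 0.176 and 0.178 from T3 replicates 1 and 2). How far the wider spread of values on T3 replicates 1 and 2 may account for it stays open, since 7 probe sets were called after quantile normalization, while the median difference of the 338 went only from 0.324 to 0.285 log2 units (median SE 0.0565 and 0.0559) and their median adjusted p became 0.0756. A ligand difference is open too. Over these probe sets T3 replicate 3 deviated from the GC-1 mean by 18.4% of the median deviation of T3 replicates 1 and 2. The direction was the same in 67.2% of them. Over the 338 probe sets with the smallest p without T3 replicate 1 or 2, that replicate deviated by 88.4% or 56.4% of the others. The 181 lower calls had medians against vehicle of 0.187 on T3 replicates 1 and 2, -0.124 on replicate 3 and -0.128 with GC-1. The 157 higher ones had -0.246, 0.001 and 0.0967. T3 replicate 3 thus lay nearer GC-1 here, but none passes with that array in the fit. Its small deviation restates the pattern and rests on that 1 array.

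The second pattern is the larger response of the T3 arrays. T3 replicate 3 had the highest score of all arrays, 0.0738 log2 units above the highest GC-1 array. Over the scored probe sets, T3 replicates 1 and 2 alone thus do not carry the pattern. T3 replicate 3 helped to choose those probe sets, however, which may raise its score, so the score does not exclude that explanation. Array spread cannot be told apart from the larger response fully, since the difference of -0.0557 was -0.0404 after quantile normalization. All 3 GC-1 arrays then still lay below all 3 T3 arrays, but narrowly. The highest GC-1 score was 0.308, while T3 replicates 1 and 2 had 0.320 and 0.310. T3 replicate 3 stood apart at 0.374, so much of the remaining difference rests on that array. With 3 arrays a group no finer test can be made. A stronger effect of T3 than of GC-1 at 10 nM and 24 h is the explanation that the design names and may be read only as a hypothesis, because 1 dose and 1 time say nothing about potency or course.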

How the results depend on the processing

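Chosen after seeing the data were the fits with T3 replicates 1 and 2 left out, the covariate, and quantile normalization with T3 replicate 3 left out. The balance of higher and lower calls turned over in some settings, as given below, and no named gene or list changed direction while past its threshold. The share within 1.5-fold, taken over the probe sets that each setting called in the ligand mean, lay between 90.0% with the covariate and 99.9% with trend and robust options, and quantile normalization and median subtraction moved the counts of changed probe sets by less than 1.5 times. Array signal over background was not examined, so what it limits stays open. The causes of the shifts were not tested, except that a fold threshold calls fewer probe sets by construction. The covariate varied within groups mainly between T3 replicate 3 and the other T3 arrays, so its values for T3 rest largely on replicate 3. The fits with T3 replicates 1 and 2 left out hold 1 T3 array, assumed to vary like the other groups, so their values for T3 rest on that array. With groups of unequal size, there and without single ligand arrays, the probe sets called in the ligand mean are not chosen independently of the difference between the ligands.

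Counts for T3, GC-1, GC-1 against T3 and the ligand mean were 1957, 1347, 22 and 2061 with trend and robust options, against 1222, 622, 0 and 1228. GC-1 gave 1100 without dim probe sets (52.0% higher, against 64.8%) and 1435 with array weights. With only the 2 groups compared T3 gave 753 and GC-1 1061. At least 1.5-fold change left 121, 86 and 107 for T3, GC-1 and the ligand mean. With T3 replicates 1 and 2 left out GC-1 gave 1061 and the ligand mean 2468, and with the covariate T3 gave 2084 and the ligand mean 2629. The share of higher calls was 44.7% for T3 and 44.5% for the ligand mean with the covariate, and 46.4% and 43.2% with T3 replicates 1 and 2 left out, against 72.7% and 65.6%. For GC-1 it was 48.5% with trend and robust options, 49.2% with array weights and 49.2% with T3 replicates 1 and 2 left out. Quantile normalization with T3 replicate 3 left out gave 7 between GC-1 and T3. Leaving out single arrays gave 661 to 1356 for T3, 274 to 1272 for GC-1, 0 to 338 for GC-1 against T3 and 582 to 1405 for the ligand mean. For the ligand mean, the counts were 603, 626 and 582 without vehicle replicate 1, 2 or 3 and 798 without GC-1 replicate 2.

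The response score difference was -0.132 with T3 replicates 1 and 2 left out, where only the T3 array with the highest score remains. It was from -0.0809 to -0.0420 without single arrays. Over the probe sets called with the covariate it was -0.0192. The covariate changed which probe sets were scored there, while the scores themselves were not adjusted for it. The correlation of changes was 0.809 without dim probe sets, 0.621 with array weights, 0.511 with the covariate, and from 0.561 to 0.750 without single arrays. Lists past the test numbered 7, 6 and 0 for T3, GC-1 and GC-1 against T3 with an estimated correlation, against 14, 10 and 7. Quantile normalization left 4 between the ligands, and leaving out single arrays 3 to 10.

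The replicate number as a block lowered the counts to 773 for T3, 347 for GC-1 and 745 for the ligand mean. The numbers do not pair the samples, since arrays with the same number had correlations of deviations from -0.262 to 0.0755, and not every array correlated best with its own number, which held in 1 of 18 comparisons of an array with another group.

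Of 122 calls of named genes, the alternatives fixed beforehand lost at most 15, under the block, when no array was left out, and at most 22 with 1 array left out, without vehicle replicate 1.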

Other observations

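All tests in this part were chosen after the results that prompted them were seen. Beside the terminal component C8B, other complement genes were higher in the mean of both ligands. Of 23 measured complement components and regulators, leaving out C8A and C8B, which prompted the list, 10 rose in the ligand mean and none fell. MBL2, the mannose-binding lectin that starts a complement pathway, was higher by 0.57 with T3 (adjusted p = 0.00757) and 0.70 with GC-1 (adjusted p = 0.00386). C5 was higher by 0.32 and 0.25, and the protease C1S by 0.44 and 0.33. C3 was higher by 0.26 with T3 and by 0.17 with GC-1, where it did not pass (adjusted p = 0.0925).

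A hypothesis that the ligands raise complement genes as a group was tested with camera in the ligand mean, adjusted over 4 lists. The list lay above other genes (adjusted p = 3.63e-08; adjusted p = 0.0229 with an estimated correlation), also without the 3 measured members that earlier lists hold (adjusted p = 2.28e-06). These values are consistent with the hypothesis, on the same arrays that prompted it.

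A hypothesis that genes repressed by insulin through FOXO factors rise was tested with a list that leaves out G6PC1, PCK1 and TNFSF10, which prompted it. Of 20 measured members 7 rose in the ligand mean and none fell, among them APOC3, FOXO1, CITED2 and GABARAPL1 (adjusted p = 1.82e-05; adjusted p = 0.0229 with an estimated correlation). Of the 20 members 7 also belong to earlier lists, and without those the adjusted p was 0.0288. Insulin-repressed genes may thus be raised as a group, although PDK4 (-0.04), IRS2 (-0.07) and PPARGC1A (0.15) did not pass in the ligand mean.

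A list of known glucocorticoid targets without KLF9, SGK1 and 5 other genes that prompted it had 3 of 17 members higher in the ligand mean, DUSP1, NFKBIA and IGFBP1. It passed narrowly (adjusted p = 0.0431), but not with an estimated correlation (adjusted p = 0.249) nor without the 3 members of earlier lists (adjusted p = 0.370), so whether the group moves remains open. The widely used targets TSC22D3 (0.03) and FKBP5 (-0.21) did not pass in the ligand mean. Interferon-stimulated genes, tested because TNFSF10 and ISG20 rose, had 1 of 24 members higher in the ligand mean, MX2, and no shift as a list was found (adjusted p = 0.508).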
